A study of Mus musculus with 21 samples.

How the data were processed

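The series holds 19 RNA-seq and 2 TCR-seq libraries from mice and from the mouse colon cancer line MC38, in 8 groups taken from the labels. RNA-seq covers colorectal tumours of mice given azoxymethane and dextran sodium sulfate (AOM/DSS, 4 libraries) and cultured MC38 cells (3 libraries). It also covers control and Galnt7-knockout MC38 tumours grown for 8 days (3 libraries each) and splenic CD8 T cells of hosts of control and of knockout tumours on day 14 (3 libraries each). TCR-seq covers 1 library of splenic CD8 T cells from each kind of host. The treatment field of the CD8 libraries titled as knockout names both kinds of inoculum, so their group was taken from their titles. No label names a sequencing batch. The titles give each tumour sample a code of its own and number the samples of the other RNA-seq groups, but no label says that each came from a separate animal or culture, so p-values measure the spread between these samples, which can in part be technical.

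Per the labels' protocols, RNA was extracted with TRIzol, mRNA was selected with oligo(dT) beads, and libraries were built with a NEBNext Ultra kit. The submitters' processing notes name FastQC, Trimmomatic, STAR, featureCounts and the genome build mm10, without versions and without saying which table each served. The authors deposited whole-number read counts per gene, not normalized, for the day-8 tumours, the CD8 T cells and the MC38 cells, per the file headers. Galnt7 and Actb lie at mm10 positions in the CD8 and MC38 tables but elsewhere in the day-8 table, whose build is not given in the sources used here, so positions from that table are not printed. For the AOM/DSS tumours the authors deposited estimated counts, of which 2713 genes hold a value that is not whole, and FPKM values (fragments scaled for gene length and library total), per the file headers. The counter of that table is not given in the sources used here. Per the labels, TCR libraries were made by 5' RACE with molecular barcodes. The authors deposited per clonotype a count and a fraction of the total count, per the file headers. Whether the counts are of molecules or of reads, and which program called the clonotypes, is not given in the sources used here. The TCR tables list CDR3 sequences that are all in frame and without a stop codon. An amino-acid sequence was missing for 662 control and 3769 knockout TRA entries and for 3 control and 224 knockout TRB entries, and was filled in by translating the CDR3 nucleotides.

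Total counts per library ran from 62.2 to 72.8 M (mega, the prefix) in the day-8 tumours, from 22.3 to 26.9 M in the CD8 T cells, from 17.4 to 22.3 M in the AOM/DSS tumours and from 26.5 to 36.0 M in the MC38 cells. Gene IDs of the day-8 and CD8 tables were matched to symbols through a reference table of gene names: 51880 of 57186 IDs (90.7%) and 54409 of 54532 IDs (99.8%) had one. In the AOM/DSS and MC38 tables, which give symbols, 97.2% and 96.4% matched. No column of any other sample was used (0 columns). Counts of all replicate pairs differed by more than sampling noise: the chi-square per gene, 1 under pure sampling, was 89.7 to 146 within groups of day-8 tumours and 5.95 to 13.5 within groups of CD8 T cells, so each library was counted once.

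Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr on the group) within each table of 3 control and 3 knockout libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene is from this fit unless another tool is named. A log2 fold change is knockout minus control, its SE is the fold change divided by the square root of the F statistic, and CPM are counts per M (mega) of library total, TMM-scaled unless said otherwise. Gene lists (37 in all, 35 used for tumours and 26 for CD8 T cells) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. Each p of a list is adjusted over the lists of that comparison. Of 632 list members 629 were in the day-8 table and 579 were tested; of 476 members used for CD8 T cells 475 were in the table and 450 were tested. Members of a list that passed over all tested genes were counted, and again with p adjusted over the list alone. FPKM of the AOM/DSS tumours, and MC38 counts divided by gene length and total (CPM per kilobase), were compared within libraries by an exact 2-sided sign-flip permutation test of log2 Galnt7 minus log2 of each other family member, whose smallest possible p is 0.125 with 4 libraries and 0.25 with 3. A TCR clonotype was a CDR3 amino-acid sequence with its V and J gene. TRA and TRB were kept apart, the deeper library was also drawn down 20 times to the depth of the shallower, and shares have exact 95% binomial (Clopper-Pearson) intervals, which cover counting error only. An absent clonotype has the upper limit that 3 counts of the total allow. With 1 TCR library per group no test was made.

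The groups, main tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule took Galnt7, then, among genes past the threshold with a mean of at least 5 CPM, with a gene name that is not a predicted model or a receptor segment, and with no overlap between the groups, the 10 with the largest rise and the 10 with the largest fall, then up to 4 members with the smallest p in each list. In tables of a single group it took the members of the Galnt, O-glycan extension and MHC class I lists, and for TCR the 5 most abundant clonotypes per chain and library. It named 154 genes in the tumours, of which 133 passed, and 115 in the CD8 T cells, of which 103 passed. Some genes that the rule named are not reported here. Genes named outside it are said to be chosen after their values were seen. Added after the data had been examined were 3 further lists (sterol synthesis, amino-acid stress response, Y-linked genes), a fit of the tumours with the mean log2 CPM of the Y-linked genes as a covariate, a count in the CD8 T cells without markers of other cells, and TCR clonotypes by CDR3 nucleotides alone.

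The fit was tested on simulated counts drawn from the means and sizes of the real libraries with 200 changed genes. With the day-8 means, over 17777 tested genes, 10.4% of the genes changed 1.5-fold, 55.2% of those changed 2-fold and 84.8% of those changed 4-fold were recovered, with 6 false calls. With the CD8 means, over 15997 tested genes, these shares were 58.2%, 70.1% and 93.9%, with 11 false calls. With no gene changed, 0 genes were called for either comparison. Of 30 random lists, 1 was called with the day-8 means and 200 changed genes and 0 in the other 3 simulations. Each simulated gene had the spread that the trend over all genes gives for its level, not a spread of its own. The real libraries also gave far more changed genes. The shares recovered and the false calls can therefore differ in the real data. The simulated genes were also drawn independently of each other. The random lists therefore cannot show how often the list test calls falsely where genes of a list move together. The alternatives were size factors of DESeq2 in edgeR, DESeq2 1.42.0 (Wald test), limma-voom, no filter on low counts, a fold of at least 2, each library left out in turn, the replicate number as a block (CD8 T cells), an estimated correlation, unscaled CPM, levels without gene length, and other definitions and depths of clonotypes. R 4.3.3, version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Biopython 1.88 and matplotlib 3.10.9 were used. Reads were not aligned again and no genome sequence was used here. Reads of overlapping or near-identical genes can be split by the counting, so values of Galnt2, Galnt4, Klra, H2, haemoglobin and Gm genes are uncertain to that extent.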

Results

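GALNT7 is one of the enzymes that attach N-acetylgalactosamine to proteins, the first sugar of mucin-type O-glycans. RNA was sequenced from 19 libraries and T-cell receptors from 2. Colorectal tumours of C57BL/6 mice (n = 4) were taken on day 70 after azoxymethane (8 mg/kg), a carcinogen, and courses of 2.5% dextran sodium sulfate, which inflames the colon. MC38, a mouse colon cancer line, was sequenced as cultured cells (n = 3). Control or Galnt7-knockout MC38 cells were injected under the skin of C57BL/6J mice. Tumours from 1 M (mega) cells were taken on day 8 (n = 3 per group). Splenic CD8 T cells of mice given 2 M cells were taken on day 14 (n = 3 per group, and 1 TCR library per group). Library totals were 62.2 to 72.8 M counts in the day-8 tumours, 22.3 to 26.9 M in the CD8 T cells, 17.4 to 22.3 M in the AOM/DSS tumours and 26.5 to 36 M in the MC38 cells.

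Galnt7 (ENSMUSG00000031608, mm10 chromosome 8, 57523828 to 57653032, minus strand) was lower in each of the 3 knockout tumour libraries than in each of the 3 control libraries. It stood at 64.3, 78.8 and 74.2 CPM in the controls (72.4 ± 7.38, SD, n = 3) and at 25.2, 31.4 and 24.5 CPM in the knockouts (27.1 ± 3.77, SD, n = 3). Galnt7 fell by 1.42 on the log2 scale (SE 0.14, adjusted p = 0.00331). These tumours contain host cells, which carry the intact gene. In CD8 T cells of the hosts, which were not edited, Galnt7 was 56.5 ± 3.05 CPM with control and 59.0 ± 4.21 CPM with knockout tumours (SD, n = 3 each), a log2 difference of 0.06 (SE 0.07, adjusted p = 0.579) that did not pass. Galnt7 was at 24.7 ± 2.75 FPKM (SD, n = 4) in AOM/DSS tumours, and MC38 cultures had 3657, 2280 and 1892 Galnt7 counts.

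**Figure D1:**
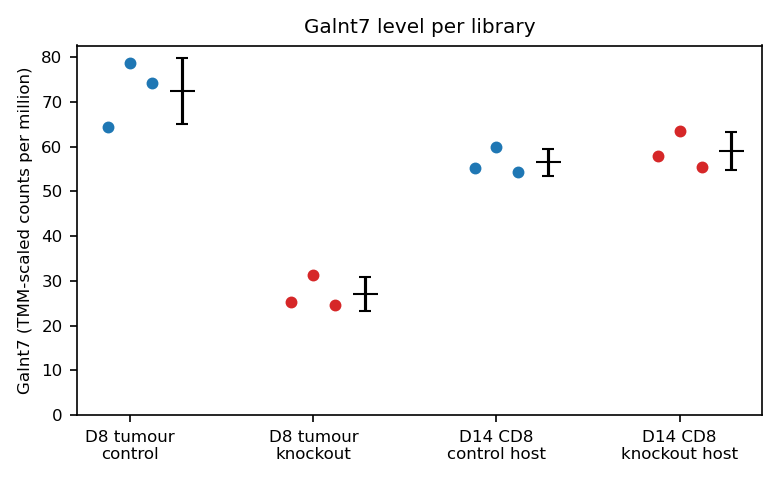
Galnt7 in TMM-scaled CPM (vertical axis) for each library (points) of the day-8 tumours and the day-14 CD8 T cells, with mean and SD of each group as a black cross with bars. The knockout tumours lie between 24.5 and 31.4, below all control tumours (64.3 to 78.8), and the CD8 groups overlap.

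The day-8 tumours address what changes in a tumour when its MC38 cells lack Galnt7. Genes of T cells and of killing functions were higher in the knockout tumours. Prf1, which encodes the pore-forming protein perforin, rose by 2.55 on the log2 scale (SE 0.36, adjusted p = 0.00829), from 6.00 ± 0.43 to 35.1 ± 17.0 CPM (SD, n = 3 each). Cd6, a T-cell surface receptor, rose by 2.48 (SE 0.34, adjusted p = 0.00744) and Gzmb, encoding granzyme B, by 2.25 (SE 0.34, adjusted p = 0.00887). Tnfrsf8, which encodes the activation receptor CD30, rose by 2.97 (SE 0.21, adjusted p = 0.000795).

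All 20 tested T-cell markers rose (20 also when adjusted over the list alone), among them Cd28 (2.09, SE 0.26) and Trbc1 (1.92, SE 0.26). The median was 2.16 (camera adjusted p = 8.41e-10). The list score (mean log2 CPM) was 1.78, 1.19 and 2.21 in the controls and 2.99, 4.18 and 4.22 in the knockouts, so knockout replicate 1 lay nearest to the controls. Cd8a, chosen after values were seen, was at 3.05 CPM in that library and at 3.22 CPM in control replicate 3. Of 24 cytotoxic effector genes 16 rose and 0 fell (adjusted over the list alone, 16 and 1), with Gzma at 1.97 (SE 0.30) and a median of 1.80 (camera adjusted p = 5.04e-06). NK-cell markers rose in 13 of 14 cases (13 adjusted over the list alone). Their median was 1.92 (camera adjusted p = 3.97e-06). The exception, Klra4, a receptor of the Ly49 family, fell by 1.62 (SE 0.19, adjusted p = 0.00551) and had 1752, 699 and 1007 counts in cultured MC38 cells. Inhibitory receptors and exhaustion genes rose in 12 of 18 cases (16 adjusted over the list alone), including Lag3 (1.96, SE 0.30), Pdcd1 (1.58, SE 0.28) and Ctla4 (1.38, SE 0.17). This list had a median of 1.35 (camera adjusted p = 3.97e-06). T-cell receptor activation genes had 9 rises and 1 fall among 20 (10 and 1 adjusted over the list alone), with Ifng at 2.60 (SE 0.52) and Xcl1 at 2.59 (SE 0.45). The median change was 1.08 (camera adjusted p = 2.22e-05). Regulatory and CD4 T-cell markers rose in 9 of 12 cases (10 adjusted over the list alone), led by Cd4 (2.29, SE 0.38). Members had a median of 1.43 (camera adjusted p = 2.15e-05). Gamma-delta T-cell markers rose in 5 of 11 cases (7 adjusted over the list alone). The list median was 1.70 (camera adjusted p = 0.000588). Each of these 7 lists had adjusted p = 0.341 with an estimated correlation.

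Interferon and antigen presentation genes were also higher. Type I interferon response genes rose in 23 of 24 cases (24 adjusted over the list alone), with Cmpk2 at 2.01 (SE 0.29), Oas2 at 1.82 (SE 0.29) and Usp18 at 1.80 (SE 0.27). The median was 1.77 (camera adjusted p = 5.92e-11). Of 23 interferon-gamma response genes 15 rose (19 adjusted over the list alone), with the chemokines Cxcl11 (1.90, SE 0.32) and Cxcl10 (1.81, SE 0.27). Their median was 1.31 (camera adjusted p = 8.79e-07). MHC class I presentation had 12 rises and 1 fall among 17 genes (15 and 1 adjusted over the list alone), including the peptide transporter genes Tap2 (1.32, SE 0.21) and Tap1 (1.25, SE 0.21) and the light chain gene B2m (0.86, SE 0.15). This list had a median of 0.80 (camera adjusted p = 1.18e-05). MHC class II genes rose in 10 of 12 cases (11 adjusted over the list alone), such as H2-Ab1 (1.69, SE 0.31) and H2-Eb1 (1.64, SE 0.29). The median change was 1.30 (camera adjusted p = 6.88e-06). Of 19 chemokine and recruitment genes 10 rose (12 adjusted over the list alone), with Ccl5 at 1.98 (SE 0.28) and Cxcl12 at 1.54 (SE 0.22). Members had a median of 1.19 (camera adjusted p = 9.00e-05). These 5 lists each had adjusted p = 0.341 with an estimated correlation.

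Markers of other host cells moved in the same direction as these groups. Macrophage and monocyte markers rose in 16 of 20 cases (17 adjusted over the list alone; median 1.09, camera adjusted p = 1.04e-06), with Fcgr1 at 1.55 (SE 0.31) and C1qa at 1.28 (SE 0.26). Dendritic-cell markers rose in 8 of 15 cases (11 adjusted over the list alone; median 1.23, camera adjusted p = 2.14e-05), with Itgax at 1.03 (SE 0.18). B-cell markers rose in 5 of 13 cases (5 adjusted over the list alone), with Cd22 at 1.88 (SE 0.34), a median of 1.28 and camera adjusted p = 0.000707. Plasma-cell markers rose in 4 of 8 cases (4 adjusted over the list alone), with Igha at 3.66 (SE 0.63), a median of 1.24 and camera adjusted p = 0.00298. Mast-cell and eosinophil markers rose in 7 of 12 cases (8 adjusted over the list alone), with Tpsb2 at 1.65 (SE 0.30), a median of 1.28 and camera adjusted p = 7.10e-05. Endothelial markers rose in 9 of 14 cases (10 adjusted over the list alone), with Plvap at 1.29 (SE 0.21), a median of 0.83 and camera adjusted p = 6.51e-05. With an estimated correlation, adjusted p = 0.351 for macrophage markers and 0.341 for the other 5 lists. Fibroblast markers rose in 10 of 18 cases (12 adjusted over the list alone), with Col3a1 at 1.29 (SE 0.27) and Thy1, which T cells also express, at 1.41 (SE 0.18), a median of 1.07 and camera adjusted p = 2.58e-05, and adjusted p = 0.360 with an estimated correlation.

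Lists with few passing members were neutrophil markers (1 of 17 rose, 1 adjusted over the list alone, median 1.2, camera adjusted p = 0.0123), with Mmp9 at 1.99 (SE 0.40), and erythroid markers (2 of 7 rose, 7 adjusted over the list alone, median 1.61, camera adjusted p = 0.00609), with Car2 at 1.88 (SE 0.23). Skeletal-muscle markers (2 of 17 rose, 0 adjusted over the list alone) had a median of 0.63 and camera adjusted p = 0.0139, and adipocyte markers (2 of 13 rose, 2 adjusted over the list alone) a median of 1.63 and camera adjusted p = 0.0229. With an estimated correlation, adjusted p = 0.552 for neutrophil, 0.399 for erythroid and 0.535 for muscle and adipocyte markers. The scores of neutrophil, muscle and adipocyte markers overlapped between the groups. The neutrophil call was lost without control replicate 2 (camera adjusted p = 0.106) or knockout replicate 1 (0.177), the muscle call without control replicate 2 (0.0720) or 3 (0.148), and the adipocyte call without control replicate 3 (0.0753) or knockout replicate 2 (0.344). Erythroid scores were 2.48, 3.89 and 2.04 in the knockouts, highest in replicate 2, and 1.67, 0.917 and 1.64 in the controls. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, chosen after values were seen, had 0 counts in cultured MC38 cells. Of these, Ddx3y rose by 0.88 (SE 0.26, adjusted p = 0.0432) and the other 3 did not pass (Kdm5d 1.10, Uty 0.89 and Eif2s3y 0.72). Ptprc, the pan-leukocyte gene for CD45, also chosen after values were seen, rose by 1.55 (SE 0.28, adjusted p = 0.0113).

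**Figure D2:**
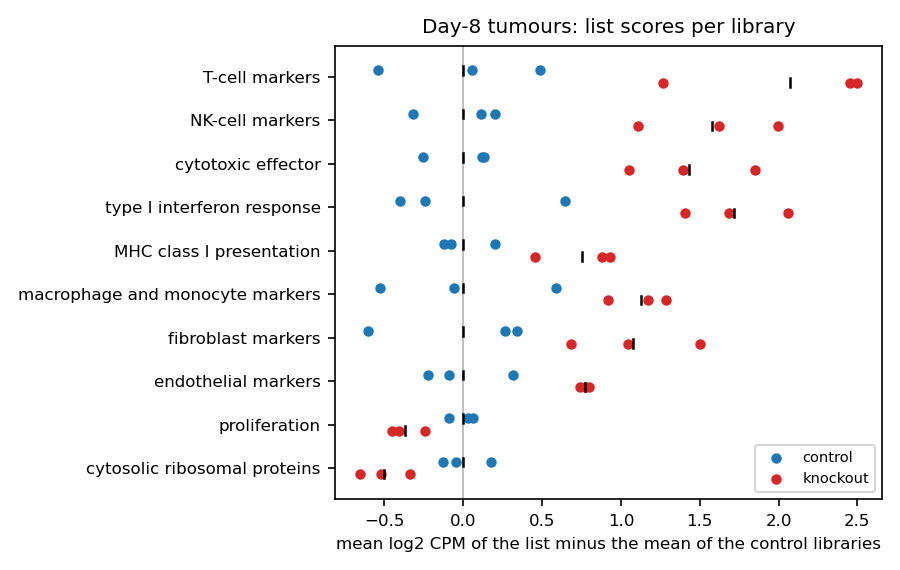
Scores of 10 gene lists, picked after the values were seen, in the day-8 tumours: mean log2 CPM of each list's genes minus the mean of the control libraries (horizontal axis), with a point per library and a black tick at the mean of each group. Scores of the knockout libraries lie above those of all controls for the top 8 lists and below them for proliferation and cytosolic ribosomal proteins.

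Genes that fell in the knockout tumours included several with counts in cultured MC38 cells. Slc6a15, an amino-acid transporter gene, had 1218, 1614 and 1449 counts in control tumours and 2, 0 and 2 counts in knockout tumours, and 859, 1280 and 421 counts in the cultures. Msln, encoding the surface protein mesothelin, fell by 2.83 on the log2 scale (SE 0.15, adjusted p = 0.000245), from 125 ± 18.2 to 17.5 ± 1.36 CPM (SD, n = 3 each). Atg9b, an autophagy gene, fell by 3.18 (SE 0.26, adjusted p = 0.00167) and the teneurin genes Tenm4 and Tenm3 by 3.15 (SE 0.27) and by 2.56 (SE 0.27). Msmo1 (-2.43, SE 0.24) and Idi1 (-2.33, SE 0.15), enzymes of sterol and isoprenoid synthesis, and Cth (-2.41, SE 0.31), an enzyme that makes cysteine, fell as well.

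Cytosolic ribosomal protein genes fell in 17 of 28 cases (18 adjusted over the list alone), for example Rpl22 (-0.98, SE 0.17) and Rpl4 (-0.77, SE 0.13). The list median was -0.53 (camera adjusted p = 2.04e-07). Their share of all counts was 8.69% to 10.8% in control and 6.28% to 7.36% in knockout tumours. Proliferation genes fell in 7 of 24 cases (9 adjusted over the list alone), such as Kif11 (-1.0, SE 0.17) and Top2a (-0.75, SE 0.15). The median was -0.33 (camera adjusted p = 0.000172). Hypoxia and glycolysis genes fell in 2 of 22 cases (1 adjusted over the list alone), Vegfa (-1.16, SE 0.32) and Ndrg1 (-1.05, SE 0.23). Their median was -0.36 (camera adjusted p = 0.0389). Scores of this list were 7.81, 7.47 and 7.35 in the controls and 7.44, 6.46 and 7.53 in the knockouts, and the call was lost without knockout replicate 2 (camera adjusted p = 0.447) or control replicate 1 (0.206). With an estimated correlation, adjusted p = 0.362 for ribosomal, 0.351 for proliferation and 0.663 for hypoxia genes.

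Within the glycosylation lists, 3 of 15 tested Galnt genes rose and 3 fell (4 and 3 adjusted over the list alone; median 0.45, camera adjusted p = 0.202). Galnt15 (-0.82, SE 0.15) and Galnt1 (-0.67, SE 0.13) fell with Galnt7, and Galnt3 rose by 1.51 (SE 0.41) from a low level of 0.935 CPM. Genes of O-glycan extension and capping had 6 rises and 1 fall among 14 (8 and 3 adjusted over the list alone), with B4galt5 at 1.10 (SE 0.14) and the sialyltransferase gene St3gal1 at 0.83 (SE 0.17), a median of 0.66 and camera adjusted p = 0.0123, and adjusted p = 0.341 with an estimated correlation. Lists that did not pass were mucins and mucin-type carriers (1 of 10 rose, 1 adjusted over the list alone, Selplg at 1.65, SE 0.28; camera adjusted p = 0.0687), extracellular matrix (6 of 20 rose, 9 adjusted over the list alone, median 0.56, camera adjusted p = 0.0561), skin markers (2 rose and 1 fell of 8, the same counts adjusted over the list alone, camera adjusted p = 0.558) and colon epithelium markers (1 of 8 rose, 1 adjusted over the list alone, camera adjusted p = 0.205). Unfolded protein response genes had 6 falls among 20 (6 adjusted over the list alone), including Trib3 (-1.84, SE 0.27) and Herpud1 (-1.21, SE 0.12), with a median of -0.10 and camera adjusted p = 0.0786. Oxidative phosphorylation genes (1 of 22 fell, 0 adjusted over the list alone, camera adjusted p = 0.545) and immediate early and heat shock genes (4 rose and 3 fell of 20, 4 and 4 adjusted over the list alone, median 0.03, camera adjusted p = 0.945) did not pass.

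Over 18239 tested genes in the tumours, 2150 rose and 2042 fell, of which 1385 and 437 changed at least 2-fold. The values of the groups did not overlap for 45.0% of genes, where chance gives 10%. The count fell to 1218 without knockout replicate 3, to 1596 without control replicate 3, to 1625 without knockout replicate 2, to 2143 without control replicate 2 and to 2207 without knockout replicate 1. Camera called 24 lists higher and 3 lower of 35, and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05 and fry called 24. With the mean of the Y-linked genes as a covariate, added after the data were seen, 13 genes passed, Galnt7 stood at -1.24 (SE 0.22, adjusted p = 0.127) and Prf1 at 3.00 (SE 0.51, adjusted p = 0.10).

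The splenic CD8 T cells, isolated on magnetic beads, address how the host's T cells differ when the tumour lacks Galnt7. In the hosts of knockout tumours Fosl2 and Maff, genes of AP-1 family transcription factors, fell by 2.42 (SE 0.09, adjusted p = 2.89e-07) and by 2.72 (SE 0.13, adjusted p = 1.63e-06) on the log2 scale, Maff from 75.5 ± 3.34 to 11.4 ± 2.73 CPM (SD, n = 3 each). Nr4a1, an early gene of receptor stimulation, fell by 1.89 (SE 0.11, adjusted p = 8.50e-06), from 482 ± 85.3 to 130 ± 10.7 CPM. Ddit4, an inhibitor of mTOR signalling, rose by 1.25 (SE 0.10, adjusted p = 3.91e-05), from 57.4 ± 7.47 to 136 ± 16.8 CPM.

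T-cell receptor activation genes had 12 falls and 1 rise among 20 (14 and 1 adjusted over the list alone), with Irf4 at -1.66 (SE 0.14), Rel at -1.07 (SE 0.07) and Egr1 at -0.98 (SE 0.12). This list had a median of -0.68 (camera adjusted p = 8.61e-05). Inhibitory receptors and exhaustion genes had 9 falls and 1 rise among 17 (9 and 1 adjusted over the list alone), with Nr4a2 at -1.97 (SE 0.13), Ctla4 at -1.72 (SE 0.15) and Tigit at -1.28 (SE 0.19). The median change was -0.50 (camera adjusted p = 0.000897). Unfolded protein response genes fell in 8 of 20 cases (8 adjusted over the list alone), including Dnajb9 (-1.21, SE 0.14), Xbp1 (-0.70, SE 0.07) and Hspa5 (-0.59, SE 0.05). Members had a median of -0.11 (camera adjusted p = 0.00923). Each of these 3 lists had adjusted p = 0.514 with an estimated correlation. Immediate early and heat shock genes had 7 falls and 1 rise among 20 (10 and 4 adjusted over the list alone), with Junb at -1.09 (SE 0.12) and Ier2 at -0.73 (SE 0.09), and a median of -0.41, and the list did not pass (camera adjusted p = 0.0791). Within it Fos (0.10, SE 0.30) and Jun (-0.38, SE 0.16), chosen after values were seen, did not pass.

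CD8 T-cell identity genes rose in 10 of 16 cases (14 adjusted over the list alone), with Cd8b1 at 0.51 (SE 0.06), Cd27 at 0.38 (SE 0.05) and Thy1 at 0.33 (SE 0.04), a median of 0.19 and camera adjusted p = 1.92e-06, and adjusted p = 0.514 with an estimated correlation. MHC class I genes rose in 5 of 17 cases (5 adjusted over the list alone), such as Nlrc5 (0.29, SE 0.04) and Tap2 (0.27, SE 0.04). The list median was 0.07 (camera adjusted p = 0.0265). Interferon-gamma response genes had 9 rises and 5 falls among 20 (11 and 5 adjusted over the list alone), with the GTPase genes Tgtp1 (0.95, SE 0.11), Irgm2 (0.84, SE 0.07) and Igtp (0.51, SE 0.06), a median of 0.26 and camera adjusted p = 0.0322. Both of these lists had adjusted p = 0.597 with an estimated correlation. The MHC class I call was lost without control replicate 1 (camera adjusted p = 0.0861), control replicate 3 (0.0699) or knockout replicate 2 (0.119). The interferon-gamma call was lost without control replicate 1 (0.108), knockout replicate 1 (0.0662) or knockout replicate 2 (0.0923), and the scores of that list overlapped between the groups. Among cytotoxic effector genes 4 rose and 5 fell of 20 (5 and 5 adjusted over the list alone), with Prf1 at 0.46 (SE 0.06) and the chemokine genes Ccl3 at -1.04 (SE 0.12) and Ccl4 at -0.87 (SE 0.09). Their median was 0.10, their mean -0.11 and the direction of the test up (camera adjusted p = 0.781). Naive and memory genes had 7 rises and 3 falls among 18 (7 and 3 adjusted over the list alone), with Cxcr3 at 0.62 (SE 0.07), Lef1 at 0.31 (SE 0.06), Ccr7 at -0.95 (SE 0.10) and Cd44 at -0.51 (SE 0.07), and did not pass as a list (median 0.07, camera adjusted p = 0.241).

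Markers of cells other than CD8 T cells moved with these groups. All 12 MHC class II genes fell (12 adjusted over the list alone), such as H2-Eb1 (-1.48, SE 0.12) and Cd74 (-1.24, SE 0.12). The median was -1.06 (camera adjusted p = 2.61e-07). B-cell markers fell in 15 of 16 cases (16 adjusted over the list alone), with Ighd at -1.23 (SE 0.21), a median of -1.29 and camera adjusted p = 7.93e-07. Plasma-cell markers fell in 6 of 11 cases (9 adjusted over the list alone), with Jchain at -1.06 (SE 0.21), a median of -0.81 and camera adjusted p = 0.000836. Dendritic-cell markers had 10 falls and 1 rise among 15 (10 and 1 adjusted over the list alone), with Siglech at -1.29 (SE 0.19), a median of -0.95 and camera adjusted p = 5.96e-05. Macrophage and monocyte markers fell in 11 of 20 cases (15 adjusted over the list alone), with Cd14 at -1.31 (SE 0.16), a median of -0.47 and camera adjusted p = 8.61e-05. Regulatory and CD4 T-cell markers fell in 7 of 12 cases (8 adjusted over the list alone), with Foxp3 at -1.01 (SE 0.20), a median of -0.62 and camera adjusted p = 0.000188. With an estimated correlation, adjusted p = 0.514 for each of these 6 lists. Neutrophil markers fell in 10 of 18 cases (16 adjusted over the list alone), with Trem1 at -2.60 (SE 0.35) and Il1b at -1.85 (SE 0.37), a median of -1.54 and camera adjusted p = 0.000152, and adjusted p = 0.590 with an estimated correlation. Control replicate 3 stood apart, with a neutrophil score of 4.57 against 3.21 and 2.95 and Il1b at 48.7 CPM against 18.3 and 15.3, and without it Il1b was at -1.14.

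Erythroid markers rose in 4 of 11 cases (6 adjusted over the list alone), with the haemoglobin genes Hbb-bs (1.44, SE 0.24) and Hba-a1 (1.19, SE 0.26), a median of 1.00 and camera adjusted p = 0.00067, and adjusted p = 0.514 with an estimated correlation. Cytosolic ribosomal protein genes fell in 7 of 28 cases (7 adjusted over the list alone), with Rpl37 at -0.25 (SE 0.04), a median of -0.10 and camera adjusted p = 0.00067, and adjusted p = 0.597 with an estimated correlation. Gm26917, chosen after values were seen, rose by 1.39 (SE 0.14, adjusted p = 0.000142). It was at 155, 115 and 179 CPM in the controls and at 412, 332 and 433 CPM in the knockout hosts. Gm26917 was also kept as a measure of library quality, and whether quality differed between the groups was not tested. Lists that did not pass were type I interferon response (2 rose and 2 fell of 24, 1 and 2 adjusted over the list alone, median -0.02, mean -0.03, test up, camera adjusted p = 0.742), the Galnt family (1 of 10 rose, 1 adjusted over the list alone, Galnt6 at 0.15, SE 0.04; median 0.07, mean -0.01, test up, camera adjusted p = 0.559) and O-glycan extension (1 of 12 fell, 0 adjusted over the list alone, camera adjusted p = 0.632). NK-cell markers (2 of 14 fell, 2 adjusted over the list alone, camera adjusted p = 0.166), gamma-delta T-cell markers (2 of 12 fell, 1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.637), proliferation (1 rose and 2 fell of 24, camera adjusted p = 0.169), hypoxia and glycolysis (1 rose and 3 fell of 21, camera adjusted p = 0.147) and oxidative phosphorylation (4 of 22 fell, camera adjusted p = 0.0791) did not pass either, and the counts of the last 3 lists were the same adjusted over the list alone.

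**Figure D3:**
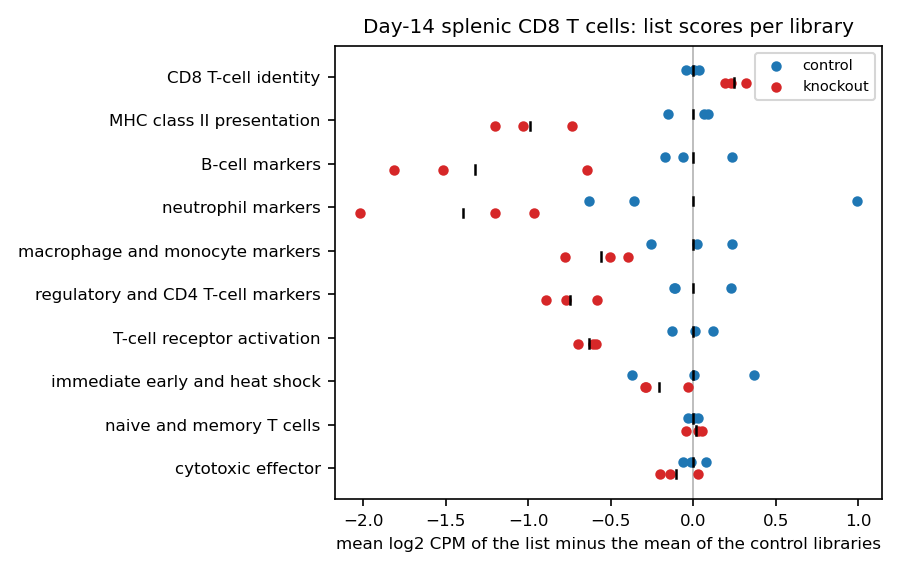
Scores of 10 gene lists, picked after the values were seen, in the day-14 splenic CD8 T cells: mean log2 CPM of each list's genes minus the mean of the control libraries (horizontal axis), with a point per library and a black tick at the mean of each group. Libraries from hosts of knockout tumours lie above all controls for CD8 T-cell identity and below them for MHC class II, B-cell, neutrophil, macrophage, CD4 T-cell and T-cell receptor activation genes, and the groups overlap for the last 3 lists.

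Over 16317 tested genes in the CD8 T cells, 1476 rose and 1745 fell, of which 56 and 496 changed at least 2-fold. The values of the groups did not overlap for 37.6% of genes, where chance gives 10%. Camera called 4 lists higher and 11 lower of 26, and 0 with an estimated correlation, where 0 lists had an unadjusted p under 0.05 (lowest 0.0873) and fry called 7. The count of changed genes fell to 1908 without knockout replicate 3, and the count of risen genes to 958 without knockout replicate 2.

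The AOM/DSS tumours and the MC38 cells show how Galnt7 stands within its family, each within its own libraries. In AOM/DSS tumours Galnt7 (24.7 ± 2.75 FPKM, SD, n = 4) ranked 4 of 19 family genes in each library, below Galnt1 (55.8 ± 3.89), Galnt3 (33.5 ± 3.42) and Galnt4 (31.1 ± 2.54) and above Galnt6 (17.6 ± 2.05) and Galnt12 (17.2 ± 1.13). Galnt7 made up 10.8% ± 1.41 of the summed family FPKM (SD, n = 4). Galnt7 was lower than those 3 genes and higher than the other 14 measured above 0 in 4 of 4 libraries, with an exact permutation p of 0.13 for each before and after adjustment, the smallest that 4 libraries allow. Galntl5 was listed at 0. Of the members of the O-glycan extension and capping list, C1galt1 (57.4 ± 1.75 FPKM), its chaperone gene C1galt1c1 (34.1 ± 5.03) and the sialyltransferase gene St6galnac6 (120 ± 10.9) were measured (SD, n = 4). Of MHC class I genes, B2m was at 1120 ± 624, H2-K1 at 546 ± 232 and Tap1 at 27.5 ± 13.5 FPKM (SD, n = 4).

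In cultured MC38 cells Galnt7 was at 15.9 ± 3.01 CPM per kilobase (SD, n = 3). Galnt2 (43.6 ± 2.58) and Galnt1 (23.0 ± 5.08) were higher in 3 of 3 libraries, and Galnt12 (10.6 ± 0.602) was lower in 3 of 3, each with an exact permutation p of 0.25 (0.306 adjusted), the smallest possible. Galnt18 (17.9 ± 11.2) and Galnt15 (14.0 ± 11.0) varied more, and Galnt7 was above each of them in 1 of 3 libraries (exact permutation p = 1). Their spread rests on library 2, where Galnt18 was at 5.02 against 25.2 and 23.5 and Galnt15 at 1.76 against 23.2 and 17.1. Library 2 also stood apart in sterol and stress genes. Galnt7 ranked 4 by mean and 5, 3 and 5 in the libraries, with 11.7% ± 2.14 of the family sum (SD, n = 3). Galnt3, Galnt5 and Galnt14 had 0 counts. MHC class I genes were measured at 623 ± 3.10 for B2m, 353 ± 79.0 for H2-D1, 197 ± 46.5 for H2-K1 and 7.70 ± 2.84 for Tap1 CPM per kilobase (SD, n = 3). B3gnt3 (44.3 ± 12.2) was above C1galt1c1 (11.2 ± 2.70) and C1galt1 (9.78 ± 1.94) among the extension genes.

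TCR-seq compared the repertoires of splenic CD8 T-cell preparations of the hosts, which can hold other T cells too. There was 1 library of each kind and no replicate check, so the values describe these libraries. The control library held 65682 TRA clonotypes in 111553 counts and 61843 TRB clonotypes in 68952 counts. The library from the host of a knockout tumour held 160725 TRA clonotypes in 378436 counts and 290770 TRB clonotypes in 410571 counts. Drawn down to the depth of the control library, it held a mean of 66035 TRA and 61544 TRB clonotypes. The 100 most abundant TRA clonotypes took 7.49% of control counts (95% interval 7.33 to 7.64) and, at equal depth, 6.61% of knockout counts (6.47 to 6.76). For TRB these shares were 1.83% (1.73 to 1.93) and 1.60% (1.51 to 1.70).

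The most abundant TRA clonotype of both libraries was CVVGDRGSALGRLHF with TRAV11 and TRAJ18, the invariant chain of natural killer T cells, at 1.87% (1.79 to 1.95) of control and 1.85% (1.80 to 1.89) of knockout counts. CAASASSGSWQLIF was second in both, at 0.521% and 0.530%. The most abundant TRB clonotype of the control library, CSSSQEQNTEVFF, took 0.12% of its counts and had 0 of 410571 counts in the other, which allows a share of up to 0.000731%. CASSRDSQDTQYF, the most abundant TRB clonotype of the knockout library, took 0.0514% there and 0.0624% of control counts, with overlapping intervals. At equal depth a mean of 12870 TRA clonotypes (19.6% of the control's) and 5842 TRB clonotypes (9.45%) were shared. Among V genes, TRAV12D-1 was in 7.46% of control and 4.47% of knockout clonotypes, TRAV7D-5 in 3.97% and 2.07%, TRBV31 in 6.51% and 4.94%, TRBV17 in 2.21% and 4.03%, and TRBV5 in 5.14% and 7.06%. For identical CDR3 nucleotide sequences of both libraries the deposited V genes matched in 47.7% of TRA and 72.6% of TRB cases and the J genes in 100%, so differences in V use and sharing rest in part on the V calls.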

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

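The comparison of T-cell markers with Y-linked genes, the test of handling and the counts over other splits of the libraries are tests chosen after the results were seen. In the AOM/DSS tumours Galnt16 was at 2.09, 2.13 and 2.14 FPKM in 3 libraries and at 1.15 FPKM in library 4, a gap of 0.9495 of the range, above Dixon's critical value for 4 samples. It was 1 of 52 genes looked at, and chance picks out about 1 in 20 groups.

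Of 24 gene lists tested in both comparisons, 10 were higher in every knockout tumour library than in every control library and lower in every CD8 library of a knockout host than in every control library. The mean log2 change in the tumours minus that in the CD8 T cells was 2.32 for MHC class II, 1.879 for inhibitory receptors and exhaustion, 1.739 for NK-cell markers, 2.237 for regulatory and CD4 T-cell markers and 1.947 for gamma-delta T-cell markers. It was 2.538 for B-cell, 2.259 for plasma-cell, 1.684 for macrophage and monocyte and 1.936 for dendritic-cell markers, and 1.652 for T-cell receptor activation. These differences were not tested. They set whole tumours of day 8 against CD8 T-cell preparations from the spleen on day 14, where markers of other cells reflect what the preparation still held. In the CD8 T cells the NK-cell (camera adjusted p = 0.166) and gamma-delta T-cell lists (camera adjusted p = 0.637) did not pass.

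T-cell markers were higher in the knockout tumours, and a larger share of host cells of every kind is a candidate explanation. The Y-linked genes, which had 0 counts in MC38 cultures, give a gauge of the host share, and their mean log2 CPM was higher by 0.97 (SE 0.39, n = 3 per group). The T-cell score minus this gauge differed by 1.10 (SE 0.67), within 2 SE of 0, with knockout replicate 1 (-1.66) inside the range of the controls (-2.28 to -1.0), so a larger host share stays open, and so does a rise of T cells beyond it. Scores minus the gauge were 0.61 (SE 0.48) for NK-cell, 0.25 (SE 0.36) for B-cell, 0.16 (SE 0.20) for macrophage, 0.11 (SE 0.24) for fibroblast and -0.20 (SE 0.48) for endothelial markers. The loss of Galnt7 in the tumour cells, the difference the design names, remains among the open explanations. A difference between MC38 cultures or clones unrelated to Galnt7 cannot be told apart from it for these markers either.

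T-cell receptor activation genes were lower in CD8 T cells of knockout hosts, together with markers of other cells, whose score fell by 0.97 (SE 0.22). Fewer B, myeloid and CD4 T cells in the preparations could lower such genes. Without a covariate the difference of the activation score was -0.63 (SE 0.08). With the score of these cells as a covariate it was -0.57 (SE 0.22, 3 residual degrees of freedom). The slope of the covariate was 0.06 (SE 0.20), too uncertain to take out an effect of these cells, and the covariate is tied to the group. The fit therefore cannot decide, and fewer such cells stay open as an explanation. Handling of the cells before lysis could also move early genes. The median of the immediate early and heat shock list was -0.41 without a camera call, its score differed by -0.21 (SE 0.23) with control replicate 1 (6.84) below all knockouts (6.91 to 7.17), and Fos (0.10) and Jun (-0.38) did not pass, so handling and the tumour's genotype cannot be told apart for these genes, since the labels do not say how or when each library was handled.

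The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. In the tumours 1 of the 10 splits gave at least 4192 genes (highest other 0) and 1 at least 27 lists (highest other 22). In the CD8 T cells 1 of the 10 gave at least 3221 genes (highest other 0) and 2 at least 15 lists (highest other 15).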

How the results depend on the processing

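The Y-linked covariate of the tumours, the count without markers of other cells and the clonotypes by CDR3 nucleotides alone were tests chosen after the results were seen. The count of changed genes in the tumours was 4073 with DESeq2 size factors in edgeR, 5145 with DESeq2, 4419 with limma-voom and 4640 without a filter on low counts. In the CD8 T cells it was 3224, 3187, 3124 and 3862, and 3512 with the replicate number as a block and 3147 without markers of other cells. A fold of at least 2 left 1822 genes in the tumours (1385 rose, 437 fell) and 552 in the CD8 T cells (56 rose, 496 fell), since it adds a condition. With an estimated correlation camera called 0 lists in either comparison (0 higher and 0 lower). The estimate was 0.91 for T-cell, 0.80 for MHC class II and 0.74 for ribosomal genes in the tumours. It was 0.84 for B-cell markers in the CD8 T cells. These values lie far above the preset of 0.01, so the camera p of such lists with the preset can be too small. For plasma-cell markers in the tumours the estimate was 0.0135, close to the preset, and the call was lost as well. Their unadjusted camera p went from 0.00179 with the preset to 0.0366. For mucins and mucin-type carriers the estimate was -0.00766, below the preset, and the unadjusted camera p still went from 0.0570 to 0.118. A higher correlation therefore cannot account for these 2 rises in p, and the loss of all calls cannot be put down to correlation alone.

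Leaving out 1 library gave 1218 to 4582 changed genes in the tumours (553 to 2545 rose, 665 to 2037 fell). The count was 2143 without control replicate 2, 1596 without control replicate 3, 2207 without knockout replicate 1, 1625 without knockout replicate 2 and 1218 without knockout replicate 3. In the CD8 T cells the range was 1908 to 2890 (829 to 1281 rose, 1079 to 1663 fell). It was lowest without knockout replicate 3, and 958 genes rose without knockout replicate 2. Lists called higher there ranged from 2 to 4, with 2 without control replicate 1 and without knockout replicate 2. Why these libraries weigh more was not tested. Of the genes picked by the rule for named genes, 133 in the tumours and 103 in the CD8 T cells passed. Of these, 76 in the tumours and 88 in the CD8 T cells kept their direction and their call in all fits other than that with the Y-linked covariate. Over the fits that leave out 1 library, a call of such a gene was lost 158 times in the tumours and 57 times in the CD8 T cells.

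With the Y-linked covariate 13 genes passed in the tumours (3 rose, 10 fell). Of these 12 were also called without it, and all 4192 genes called without it had the same sign in this fit. The other calls ended as the median size of the change became 0.763 of that without it, the median SE went from 0.189 to 0.275 and the residual degrees of freedom from 4 to 3, with a covariate tied to the group. Galnt7 went from -1.42 (SE 0.14) to -1.24 (SE 0.22), Gzmb from 2.25 (SE 0.34) to 2.50 (SE 0.50), Cmpk2 from 2.01 (SE 0.29) to 1.66 (SE 0.42) and H2-Eb1 from 1.64 (SE 0.29) to 1.25 (SE 0.40). Changes that shrank more in proportion included Col3a1 (1.29, SE 0.27, to 0.52, SE 0.28), Oas2 (1.82, SE 0.29, to 1.01, SE 0.22) and Fcgr1 (1.55, SE 0.31, to 0.91, SE 0.34). They also included C1qa (1.28, SE 0.26, to 0.81, SE 0.31), St3gal1 (0.83, SE 0.17, to 0.48, SE 0.23), Cd22 (1.88, SE 0.34, to 1.21, SE 0.46) and Rpl22 (-0.98, SE 0.17, to -0.64, SE 0.24). Msln (-2.57, SE 0.20) and Tnfrsf8 (2.57, SE 0.31) passed in both fits. Cdh1, which did not pass in any of these fits, was at -0.09, at 0.33 with the covariate and between -0.25 and 0.03 with 1 library left out, above 0 without control replicate 3 (0.033) and without knockout replicate 1 (0.0087). The cause was not tested.

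The share of the 100 most abundant TRA clonotypes was 13.8% (control) and 9.18% (knockout) among clonotypes seen at least 2 times and 6.56% and 5.69% by CDR3 nucleotides. For TRB it was 10.8% and 3.43%, and 1.55% and 1.2%. These shares are at full depth, which differs between the libraries (TRA 111553 and 378436 counts, TRB 68952 and 410571). Drawn to the depth of the control library, the knockout library gave 6.61% for TRA and 1.60% for TRB. By counts in place of clonotypes the knockout minus control difference was 0.350 percentage points for TRAV12-2 (-0.614 by clonotypes), -0.156 for TRBJ1-5 (0.0497) and -0.180 for TRBJ2-2 (0.0771). The absolute TRB J differences, summed and divided by 2, came to 1.65% by counts (0.692% by clonotypes). Shared clonotypes at equal depth numbered 8200 for TRA and 2245 for TRB by CDR3 nucleotides with V and J. By nucleotides alone they numbered 17327 for TRA, above the 12870 of the main definition, and 3197 for TRB. At full depth 28963 TRA nucleotide sequences were shared, and 13808 with V and J as well. J genes of shared sequences matched in 100% of cases and V genes in 47.7%, so V calls that differ lower the TRA counts that require V. Why the V calls differ was not tested. The choice between in-frame and all clonotypes could not be run, as the tables hold no others, and choices planned for tables without counts did not apply. Of simulated 1.5-fold changes, 10.4% were recovered for the tumours and 58.2% for the CD8 T cells. Depth limits what can be said of absent clonotypes, with a share of up to 0.000731% left open for TRB in the knockout library.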

Other observations

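The sterol and amino-acid stress lists and the comparison with MC38 cultures were tests chosen after the results were seen, and the test of a smaller share of tumour cells was chosen before its result. Genes of sterol synthesis and uptake were lower in the knockout tumours. Of 24 such genes 21 fell and 0 rose, with a median log2 change of -1.33 (camera adjusted p = 6.89e-15, adjusted p = 0.335 with an estimated correlation, fry adjusted p = 0.000688). Fdps fell by 2.13 (SE 0.15), Sqle by 2.00 (SE 0.14) and Hmgcs1 by 1.57 (SE 0.16), all chosen after their values were seen. Of 22 genes of the amino-acid and integrated stress response 15 fell and 0 rose, with a median of -0.76 (camera adjusted p = 6.26e-07, adjusted p = 0.335 with an estimated correlation, fry adjusted p = 0.0233), among them Chac1 (-2.03, SE 0.25), also chosen after its value was seen.

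Among the MC38 cultures, library 2 stood apart. Its sterol score (mean log2 CPM) was 4.60 against 6.57 and 6.70, and its stress score 8.35 against 5.65 and 6.06. It had 22382 counts of Chac1 against 1404 and 1707, 12234 of Trib3 against 950 and 1037, and 13162 of Txnip against 918 and 1022. In the AOM/DSS tumours immune genes varied between libraries, with Ptprc at 50.6, 12.8, 40.8 and 16.4 FPKM and Jchain at 2999, 366, 917 and 81.7 FPKM.

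In CD8 T cells of knockout hosts, genes chosen after their values were seen included the costimulatory receptor gene Cd28 (-1.41, SE 0.08), the clock gene Per1 (-1.61, SE 0.10), Cd4 (-1.59, SE 0.33) and Txnip (0.76, SE 0.05), which all passed. In the tumours Cd274, encoding PD-L1, was at 1.47 (SE 0.52, adjusted p = 0.0735) and did not pass.

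A smaller share of tumour cells is a candidate explanation for the lower sterol genes, tested against 10000 random lists of the same size. These were drawn from 605 genes of MC38 cells that CD8 T cells lack and that no marker list holds. Each had a mean level in the tumours no higher than in MC38 cells. The sterol median (-1.33) minus the median over these lists was -0.90. The lowest of the lists was at -0.94, above the sterol median, so the sterol genes fell further than these lists. The median of the 605 genes was -0.43. A smaller share lowers genes made only by tumour cells alike, so these values argue against it as the whole account of the fall in the sterol genes. The sterol list was written after the data had been examined. The pool can also hold genes of host cells other than CD8 T cells, so the size of a fall by a smaller share is not known. A smaller share stays open as a part of the fall. A difference between MC38 cultures or clones unrelated to Galnt7 was set against the sterol score of unedited MC38 cells, whose range of 2.09 rests on library 2 (4.60 against 6.57 and 6.70), while the tumour groups differed by -1.26 (SE 0.06). In library 2 the stress score was the highest of the 3, whereas stress genes fell with the sterol genes in the knockout tumours. Knockout cells in culture were not analysed here, so a clone difference and the loss of Galnt7 cannot be told apart for these genes.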
